A study of Mus musculus with 62 samples.

How the data were processed

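Liver samples of 62 mice in 10 groups of surgery and diet were labelled, and 57 of them had a column in the deposited table of counts. The other 5 (1 sham P36, 1 SG P21, 1 sham P7 and 2 sham chow) were not analysed here. Per the labels' protocols, polyadenylated RNA was made into stranded TruSeq libraries and read in pairs of 150 bases on a NovaSeqX. The mice were randomised and each library carries its own number in the labels, so libraries were taken as separate animals. Mice were housed in pairs, and which shared a cage is not given in the sources used here.

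The deposited values are expected counts per gene, which need not be whole, for 56884 Ensembl gene IDs, and the name of the sheet the authors deposited says that RSEM made them. The genome build was GRCm39, and R 4.4.1, edgeR and limma were used, per the submitters' processing notes, which give these tools no role. The aligner, the annotation and any filter were not given in the sources used here. Multi-mapped reads are shared out by such a count, so that genes with near-identical copies are uncertain. The authors' deposited table of comparisons holds log2 fold changes of SG against sham on P36, P21 and P7 for 15523 genes. It also holds the authors' p-values and adjusted p-values from an empirical Bayes test, and an F score over the comparisons. Its model, normalization and filter are not stated, and its values were used only beside those computed here.

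Gene symbols came from the authors' deposited table for 15523 IDs and from the GENCODE annotation of GRCm38 for 36760, while 4601 had none. As builds differed, no coordinates are given. Columns were matched to samples by name, and 0 columns were left unmatched.

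Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 16087, and libraries were scaled by TMM. The 9 groups with more than 1 library were fitted together by edgeR's quasi-likelihood method, with 47 residual degrees of freedom. The design, fixed before the data were examined as were the gene lists, the named-gene rule and the first set of alternatives, assumed 61 libraries in this fit, and 56 entered it. The biological coefficient of variation was 28.2%. Each comparison was a contrast of group means, the effect over 3 diets a mean of their contrasts, and each interaction a difference of contrasts (an F test over P36, P21 and P7). P-values are two-sided and adjusted by Benjamini and Hochberg's method over the genes tested, with 0.05 as the threshold. CPM values used the TMM library sizes, with a prior count of 2 on the log2 scale.

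Named genes are, in each comparison, the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1, without predicted, pseudogene, immunoglobulin and T cell receptor symbols. Up to 4 members with the lowest adjusted p of each list that is described, and a set of metabolic genes fixed in advance, were added. The text gives some of them, and a few results are not reported here.

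For 38 gene lists of pathways and cell types, limma 3.58.1 gave fry's test on voom weights. It tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Camera, which does compare them, was run with a preset correlation of 0.01 and with an estimated one. Of the fry calls in the text, the ATF4 targets in 3 of the comparisons of P7 and the periportal markers for P7 against P36 in sham mice and for SG on P7 also passed with an estimated correlation. Lists are adjusted over the 38 of a comparison, and 17 members were matched by an alias.

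Alternatives were RLE scaling, no filter beyond 1 count (30127 genes), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone and leaving out each library in turn. Added after seeing the data were limma-voom without scaling and fits without libraries that lay apart. Chance was checked with 100 splits of the libraries of each comparison. The overlap of calls by chance is that of independent lists of the same lengths.

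The steps were tested on simulated counts with 200 changed genes. Library sizes were the real ones, and apart from the changes each gene had a single mean and spread over all groups. The spread of a single group was thus not in the simulation. On WD the SG comparison recovered 73.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 false calls of 179. On P36 these were 23.9%, 74.6% and 92.4%, with 5 false calls of 132, and on P21 52.2%, 83.6% and 97%, with 11 of 166. On P7 they were 58.2%, 82.1% and 93.9%, with 9 false calls of 165. The P36 groups, with 5 and 4 libraries, were the least able to show small changes. SG P21 library 4 had 6.99 M counts, the fewest of all. Pairs of libraries within groups were compared for duplicates, and in none of 156 pairs were the counts as close as sampling noise (lowest chi-square per degree of freedom 9.34 over genes with at least 20 counts).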

Results

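Gene expression was measured by RNA sequencing in the livers of male C57BL/6J mice, an inbred strain that becomes obese on rich food. The mice ate a Western diet (WD, 42% of calories from fat and 15.2% from protein) for 12 weeks from 5 weeks of age. At 17 weeks they had either a sham operation or a sleeve gastrectomy (SG), a weight-loss operation that here took out about 75% of the stomach. From day 7 after surgery they stayed on WD or ate 1 of 3 diets with 20% of calories from fat. Protein gave 36%, 21% or 7% of the calories of these diets, called P36, P21 and P7, and carbohydrate made up the difference. A further set of mice was labelled chow, a diet whose make-up was not given in the sources used here. Liver was taken 14 weeks after surgery, after a 16 h fast and 4 h of refeeding. The design asks how the amount of protein eaten after surgery changes the liver in sham and SG mice.

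Total counts are given in M (mega). Of 62 labelled samples 57 had a column of counts, and 56 were compared. There were 8 sham WD libraries (21.08 to 26.89 M counts each), 8 SG WD libraries (20.27 to 33.28 M) and 5 sham P36 libraries (23.95 to 26.5 M). The other protein-diet groups were 4 SG P36 libraries (22.12 to 27.28 M), 7 sham P21 libraries (14.03 to 29.69 M), 6 SG P21 libraries (6.99 to 26.31 M), 7 sham P7 libraries (24.3 to 30.65 M) and 7 SG P7 libraries (23.01 to 33.36 M). Sham chow had 4 libraries (27.38 to 34.01 M). The single SG chow library (27.93 M) entered no comparison. Fold changes are log2 values ± standard error, and levels are CPM, counts scaled to the size of the library, given as mean ± SD over the libraries of a group.

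**Figure D1:**
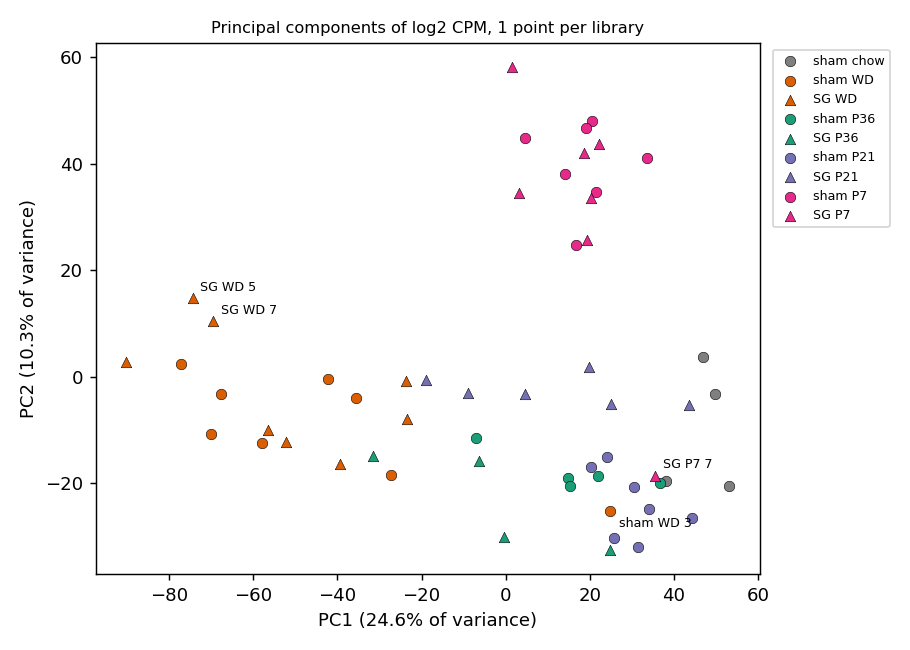
Each point is 1 of the 56 libraries, placed by its scores on the first principal component (24.6% of the variance, horizontal axis) and the second (10.3%, vertical axis) of log2 CPM, with colour for the diet and shape for the surgery. SG P7 library 7 and sham WD library 3 lie among libraries of other diets, and SG WD libraries 5 and 7 are named because some of their genes lay apart from the rest of the group.

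The livers of WD-fed sham mice carried transcripts of fat storage, macrophages and scar tissue at many times the level in chow-fed sham mice, and nearly all genes of cholesterol synthesis were lower. Cidea, a protein of lipid droplets, rose from 0.399 ± 0.35 CPM on chow (n = 4) to 65.1 ± 30.1 CPM on WD (n = 8), a log2 fold change of 7.31 ± 1.23 (adjusted p = 1.05e-05). Gpnmb, made by lipid-loaded macrophages, rose by 6.39 ± 0.94 (adjusted p = 1.2e-06), and Mmp12, an elastase of macrophages, by 6.08 ± 0.95 (adjusted p = 2.94e-06). Sqle and Idi1, enzymes of cholesterol synthesis, had log2 fold changes of -5.62 ± 0.75 (adjusted p = 1.88e-07) and -5.49 ± 0.71 (adjusted p = 1.19e-07). The highest of the 8 WD libraries held 2.93 CPM of Sqle and the lowest of the 4 chow libraries 80.4 CPM. In all, 5094 of 16087 genes were called between these groups, 2758 higher and 2336 lower on WD.

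Gene lists moved with them. All 12 measured markers of lipid-associated macrophages rose on WD, 12 also when adjusted over the list alone (median log2 fold change 2.65, fry adjusted p = 2.74e-06, adjusted p = 0.143 with an estimated correlation). Trem2, a lipid receptor of these cells, rose by 4.66 ± 0.56 (adjusted p = 2.21e-08). Of 29 fibrosis genes 24 rose, 25 adjusted over the list alone (median 1.62, fry adjusted p = 1.48e-05, adjusted p = 0.143 with an estimated correlation), among them the collagen gene Col1a1 by 4.25 ± 0.67 (adjusted p = 3.98e-06). Of 25 genes of cholesterol synthesis 24 fell, 25 adjusted over the list alone (median -2.45, fry adjusted p = 2.74e-06, adjusted p = 0.143 with an estimated correlation). Fatty acid synthesis had 12 of 21 genes higher and 2 lower, 12 and 2 adjusted over the list alone (median 0.64, fry adjusted p = 0.00056, adjusted p = 0.266 with an estimated correlation), with Scd1, which desaturates fatty acids, up by 2.89 ± 0.43 (adjusted p = 1.71e-06). The urea cycle list had 5 of 8 genes lower, 6 adjusted over the list alone (median -0.47, fry adjusted p = 0.000104, adjusted p = 0.231 with an estimated correlation). The mitochondrial share of counts was 6.06% to 9.73% in sham WD and 9.86% to 13.13% in sham chow libraries.

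Sham mice moved from WD to P21 after surgery had higher transcripts of cholesterol synthesis and lower ones of macrophages, scar tissue and lipid droplets. Sqle stood at 141 ± 40.9 CPM on P21 (n = 7) against 1.89 ± 0.671 CPM on WD (n = 8), a log2 fold change of 6.21 ± 0.73 (adjusted p = 1.42e-08), and Idi1 rose by 5.78 ± 0.69 (adjusted p = 1.68e-08). The lowest P21 library held 62.7 CPM of Sqle, above the 2.93 CPM of the highest WD library. Ly6d, a surface protein, fell with a log2 fold change of -5.67 ± 0.67 (adjusted p = 1.68e-08). Ubd, a ubiquitin-like protein of inflammation, fell with -5.34 ± 0.59 (adjusted p = 4.36e-09), and Themis, a T cell signalling protein, with -4.2 ± 0.51 (adjusted p = 3.04e-08). There were 5171 genes called, 2313 higher and 2858 lower on P21. The diets differ in fat, carbohydrate and protein at once, so none of these can be named as the part that counts.

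All 25 cholesterol genes rose on P21 in sham mice, 25 also when adjusted over the list alone (median 3.13, fry adjusted p = 9.68e-10, adjusted p = 0.0897 with an estimated correlation). Srebf2, the transcription factor that drives the pathway, rose by 1.69 ± 0.18 (adjusted p = 3.45e-09) and Stard4, a cholesterol carrier, by 2.32 ± 0.2 (adjusted p = 7.36e-12). Of 12 markers of lipid-associated macrophages 11 fell, 11 adjusted over the list alone (median -2.27, fry adjusted p = 1.61e-06, adjusted p = 0.149 with an estimated correlation). Of 29 fibrosis genes 22 fell, 24 adjusted over the list alone (median -1.17, fry adjusted p = 6.87e-05, adjusted p = 0.219 with an estimated correlation), and Col1a1 had a log2 fold change of -3.35 ± 0.5 (adjusted p = 1.76e-06). Of 27 proliferation genes 25 fell, 25 adjusted over the list alone (median -1.71, fry adjusted p = 8.25e-06, adjusted p = 0.149 with an estimated correlation). All 7 genes of MHC class II, which present antigen, fell, 7 adjusted over the list alone (median -1.97, fry adjusted p = 3.53e-06, adjusted p = 0.149 with an estimated correlation). Of 18 lipid droplet genes 12 fell, 13 adjusted over the list alone (median -0.87, fry adjusted p = 1.29e-05, adjusted p = 0.149 with an estimated correlation). Cidec, a droplet protein, went from 160 ± 61.6 to 23 ± 8.58 CPM. The mitochondrial share of counts was 6.06% to 9.73% in sham WD and 6.35% to 10.78% in sham P21 libraries.

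In SG mice the same diet change called 4744 genes, 1998 higher and 2746 lower on P21. Hsd3b5, a steroid dehydrogenase of male mouse liver, rose from 7.25 ± 9.02 CPM on WD (n = 8) to 72.5 ± 26.8 CPM on P21 (n = 6), a log2 fold change of 3.33 ± 0.96 (adjusted p = 0.00773). Cyp4a14, which oxidizes fatty acids, rose by 2.49 ± 0.38 (adjusted p = 8.11e-06). Cidec fell with a log2 fold change of -3.18 ± 0.54 (adjusted p = 2.85e-05) and Themis with -4.26 ± 0.56 (adjusted p = 8.07e-07). Of 18 lipid droplet genes 14 fell, 16 adjusted over the list alone (median -1.08, fry adjusted p = 2.94e-05, adjusted p = 0.371 with an estimated correlation). Of 10 adipocyte markers 4 fell as well, 4 adjusted over the list alone (median -0.94, fry adjusted p = 0.369, and 0.0226 with a median of -1.35 without SG WD libraries 5 and 7), among them Cfd, a complement factor of fat cells, with -6.2 ± 1.32 (adjusted p = 0.000487). Markers of other tissues fell beside them, 4 of 8 erythroid ones, 7 adjusted over the list alone (median -1.43, fry adjusted p = 0.00228, adjusted p = 0.436 with an estimated correlation), and 6 of 7 of skeletal muscle, 6 adjusted over the list alone (median -4.9, fry adjusted p = 0.699), whose mean was 2.64 log2 CPM in SG WD library 4 and -3.19 to -2.27 in the other 7 of its group. Of 25 cholesterol genes 21 rose, 22 adjusted over the list alone (median 1.27, fry adjusted p = 2.94e-05, adjusted p = 0.371 with an estimated correlation). Without SG WD libraries 5 and 7 the median of this list was 2.53 and 24 genes rose. Of 25 genes with male-predominant expression 9 rose, 9 adjusted over the list alone (median 0.78, fry adjusted p = 0.00705, adjusted p = 0.445 with an estimated correlation). The mitochondrial share of counts was 5.57% to 9.65% in SG WD and 6.88% to 12.81% in SG P21 libraries. Without SG WD libraries 5 and 7, 3 of 13 mitochondrially encoded genes rose and 0 fell (median 0.44, fry adjusted p = 0.0477).

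Across the genes tested in both, the log2 fold changes from WD to P21 correlated between sham and SG mice with Pearson's r = 0.65 and Spearman's rho = 0.69. Genes are not independent replicates, so no p-value is attached. Both comparisons called 1110 genes higher, against 287 by chance, and 1530 lower, against 488 by chance, while 17 went opposite ways. These comparisons share no library.

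**Figure D2:**
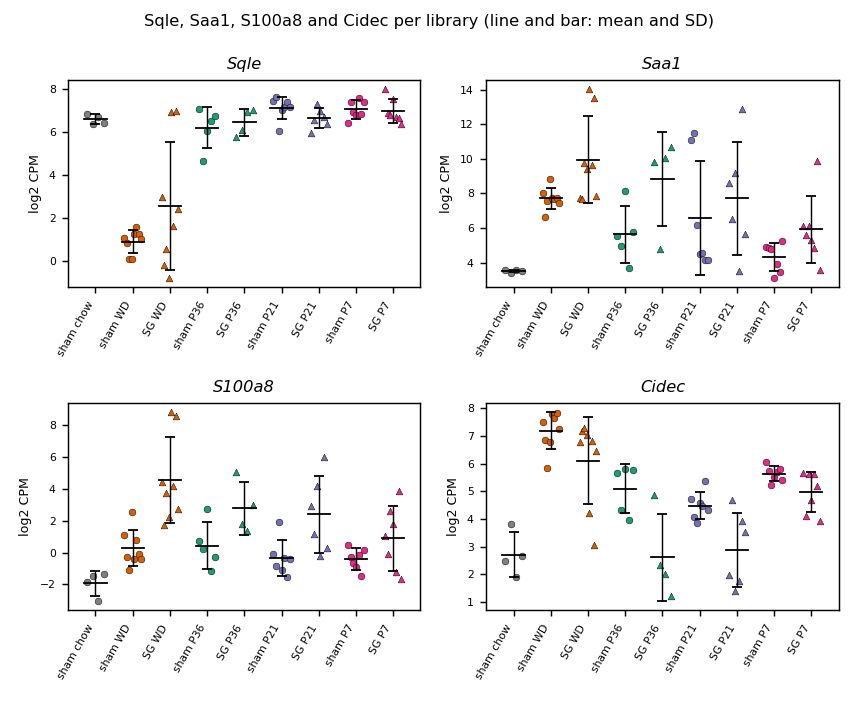
Log2 CPM (vertical axis) of Sqle, Saa1, S100a8 and Cidec in each library, by group (horizontal axis), with the mean and SD of the log2 values as line and bar. SG WD libraries 5 and 7 had Sqle at 6.93 and 6.95, against -0.80 to 2.94 in the other 6 of their group.

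Among sham mice, P7, with carbohydrate in place of protein, raised genes that cells are known to switch on when amino acids run short. Trib3, a target of the transcription factor ATF4, rose from 2.67 ± 0.541 CPM on P36 (n = 5) to 85.8 ± 29.9 CPM on P7 (n = 7), a log2 fold change of 5 ± 0.46 (adjusted p = 1.81e-11). The lowest P7 library held 52.3 CPM and the highest P36 library 3.5 CPM. Psat1, of serine synthesis, rose by 5.1 ± 0.55 (adjusted p = 1.75e-09), and Asns, asparagine synthetase, by 4.69 ± 0.7 (adjusted p = 2.78e-06). Fgf21, a liver hormone induced by low protein intake, went from 4.39 ± 3.08 to 70.5 ± 70.2 CPM, a log2 fold change of 4 ± 0.69 (adjusted p = 3.07e-05). Alas1, the first enzyme of haem synthesis, fell from 2080 ± 635 to 218 ± 106 CPM, a log2 fold change of -3.26 ± 0.38 (adjusted p = 1.08e-08). In all, 2522 genes were called, 1204 higher and 1318 lower on P7.

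Of 33 measured ATF4 and integrated stress response targets 23 rose on P7 and none fell, with 24 rising when adjusted over the list alone (median 1.75, fry adjusted p = 2.2e-08, adjusted p = 0.0178 with an estimated correlation). Among them were Ddit3, a stress transcription factor, up by 2.69 ± 0.28 (adjusted p = 1.05e-09), and Slc3a2, an amino acid transporter subunit, up by 1.66 ± 0.16 (adjusted p = 3.27e-11). Of 14 periportal markers, which include enzymes of amino acid breakdown, 7 fell, 9 adjusted over the list alone (median -0.65, fry adjusted p = 2.2e-08, adjusted p = 0.0171 with an estimated correlation). Hal, which degrades histidine, had a log2 fold change of -1.25 ± 0.23 (adjusted p = 8.72e-05) and Aldh1b1, a mitochondrial dehydrogenase, one of -2.41 ± 0.28 (adjusted p = 1.06e-08). Of 54 genes of amino acid breakdown 18 fell and 1 rose, 20 and 2 adjusted over the list alone (median -0.31, fry adjusted p = 0.00904, adjusted p = 0.632 with an estimated correlation). Of 21 genes of the unfolded protein response 15 fell, 17 adjusted over the list alone (median -0.8, fry adjusted p = 0.00107, adjusted p = 0.352 with an estimated correlation). Fatty acid synthesis had 7 of 21 genes lower, 8 lower and 1 higher adjusted over the list alone (median -0.5, fry adjusted p = 0.023, adjusted p = 0.657 with an estimated correlation). Scd1 fell from 5860 ± 1470 to 1420 ± 585 CPM, a log2 fold change of -2.04 ± 0.36 (adjusted p = 3.69e-05).

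The same diets compared in SG mice gave 3026 called genes, 1635 higher and 1391 lower on P7. Trib3 rose from 1.95 ± 1.45 CPM on P36 (n = 4) to 57.2 ± 34.5 CPM on P7 (n = 7), a log2 fold change of 4.88 ± 0.51 (adjusted p = 6.18e-10). Fgf21 rose from 0.298 ± 0.203 to 41.5 ± 25.1 CPM, by 7.08 ± 0.99 (adjusted p = 6.07e-07). The core clock repressor Nr1d1 rose by 2.77 ± 0.27 (adjusted p = 7.05e-11) and the clock output Dbp by 2.69 ± 0.37 (adjusted p = 5.71e-07), while Cry1, another clock repressor, fell with -2.26 ± 0.23 (adjusted p = 4.17e-10). Mt2 and Hmox1, which respond to metals and haem, had log2 fold changes of -4.41 ± 1.14 (adjusted p = 0.00409) and -4.1 ± 0.55 (adjusted p = 3.74e-07). Both rested on SG P36 library 1, without which they were 1.29 and -0.67.

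Among the lists in SG mice, 16 of 33 ATF4 targets rose on P7, 18 adjusted over the list alone (median 0.88, fry adjusted p = 6.73e-05, adjusted p = 0.28 with an estimated correlation). Without SG P36 library 1, 21 of them rose (median 1.56, fry adjusted p = 1.47e-05). Of 21 genes of fatty acid synthesis 15 fell and 2 rose, 15 and 2 adjusted over the list alone (median -1.08, fry adjusted p = 0.000253, adjusted p = 0.28 with an estimated correlation). Acly, which makes the acetyl-CoA for this pathway, fell from 763 ± 452 to 140 ± 52.4 CPM with a log2 fold change of -2.45 ± 0.37 (adjusted p = 2.41e-06). Fatty acid oxidation and PPARA targets had 21 of 32 genes higher and 1 lower, 23 and 1 adjusted over the list alone (median 0.77, fry adjusted p = 0.000379, adjusted p = 0.328 with an estimated correlation). Cyp4a31, a fatty acid hydroxylase, rose from 12 ± 4.24 to 99 ± 40.5 CPM, by 3.04 ± 0.37 (adjusted p = 3.29e-08). Of 8 urea cycle genes 4 fell, 4 adjusted over the list alone (median -0.5, fry adjusted p = 0.000379, adjusted p = 0.28 with an estimated correlation), among them Cps1, its first enzyme, with -1.24 ± 0.27 (adjusted p = 0.000852). SG P7 library 7 lay far from the other 6 P7 libraries of its group. Its 0.688 CPM of Fgf21 was the lowest value of the group, whose highest was 84.8 CPM, and Trib3 reached 4.17 CPM at the lowest.

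From P36 to P7 the fold changes in sham and SG mice correlated across genes with r = 0.58 and rho = 0.54. Both comparisons called 692 genes higher, against 122 by chance, and 633 lower, against 114 by chance, and 4 went opposite ways.

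**Figure D3:**
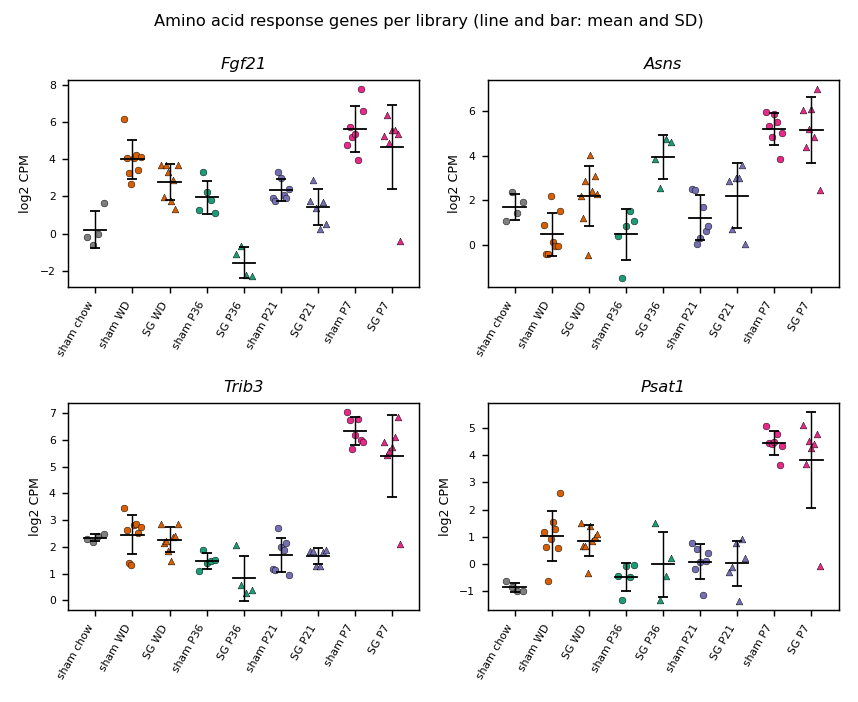
Log2 CPM (vertical axis) of Fgf21, Asns, Trib3 and Psat1 in each library, by group (horizontal axis), with the mean and SD of the log2 values as line and bar. Trib3 ran from 5.65 to 7.04 in sham P7 and from 1.08 to 1.89 in sham P36, and in SG P7 library 7 lay at 2.10 while the other 6 ran from 5.43 to 6.87.

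Against P21 instead of P36, P7 raised ATF4 targets in sham mice, with 4236 genes called, 2087 higher and 2149 lower. Trib3 rose by 4.63 ± 0.39 (adjusted p = 4.49e-13), Psat1 by 4.45 ± 0.46 (adjusted p = 3.4e-10) and Fgf21 by 3.74 ± 0.59 (adjusted p = 4.65e-06). Of 33 ATF4 targets 24 rose, 28 adjusted over the list alone (median 1.69, fry adjusted p = 9.46e-10, adjusted p = 0.041 with an estimated correlation). Of 21 genes of the unfolded protein response 18 fell, 18 adjusted over the list alone (median -1.18, fry adjusted p = 2.63e-06, adjusted p = 0.234 with an estimated correlation). Hyou1, a chaperone of the endoplasmic reticulum, fell from 619 ± 291 to 134 ± 30.5 CPM, and Derl3, which helps to clear misfolded proteins, had a log2 fold change of -4.65 ± 0.76 (adjusted p = 8.63e-06). Sham P21 libraries 1 and 2 had the highest Derl3 of their group, and without them 17 genes of the list fell (median -0.86, fry adjusted p = 0.000313), Derl3 with -3.58 (adjusted p = 0.000342). Of 30 interferon response genes 17 fell, 18 adjusted over the list alone (median -0.61, fry adjusted p = 0.000282, adjusted p = 0.45 with an estimated correlation), with Irf7, an interferon regulator, going from 44.6 ± 9.73 to 18.7 ± 8.5 CPM. Igf1, a growth factor made by the liver, had a log2 fold change of -0.5 ± 0.14 (adjusted p = 0.00728).

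In SG mice P7 against P21 called 1561 genes, 886 higher and 675 lower on P7. Trib3 rose by 4.12 ± 0.41 (adjusted p = 2.5e-10), Psat1 by 4.06 ± 0.48 (adjusted p = 3.9e-08) and Fgf21 by 3.61 ± 0.64 (adjusted p = 0.00013). Of 33 ATF4 targets 22 rose, 24 adjusted over the list alone (median 1.56, fry adjusted p = 3.65e-06, adjusted p = 0.0308 with an estimated correlation). The unfolded protein response had 10 of 21 genes lower, 17 adjusted over the list alone (median -0.78, fry adjusted p = 0.00836, adjusted p = 0.468 with an estimated correlation; 16 lower and a median of -1.04 without SG P7 library 7), and the interferon list 8 of 30 lower, 17 adjusted over the list alone (median -0.57, fry adjusted p = 0.00253, adjusted p = 0.405 with an estimated correlation). Pdia3, a disulfide isomerase, fell from 918 ± 45.1 to 473 ± 136 CPM. The count of called genes was 944 without SG P7 library 1 and 951 without SG P21 library 3, and 1021 without the filter on low counts.

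Between P36 and P21, 14 genes were called in sham livers, 11 higher and 3 lower on P36, and 1461 at an unadjusted p under 0.05. Hspa8, a chaperone of the heat shock family, stood at 3360 ± 444 CPM on P36 (n = 5) and 1620 ± 287 CPM on P21 (n = 7), a log2 fold change of 1.05 ± 0.19 (adjusted p = 0.00537). Its lowest P36 value of 2710 CPM lay above its highest P21 value of 2110 CPM. Inhba, a subunit of activin, had a log2 fold change of -1.31 ± 0.28 (adjusted p = 0.0294), and an adjusted p of 0.152 without sham P36 library 1. None of the 38 lists passed fry's test. The count of calls ran from 4 without sham P21 library 5 or 6 to 24 without sham P36 library 5, and was 3 without sham P21 libraries 1 and 2, 4 by limma-voom, 36 by DESeq2 and 62 by a fit of these groups alone.

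In SG mice the step from P21 to P36 called 1237 genes, 592 higher and 645 lower on P36. Acmsd, an enzyme of tryptophan breakdown, rose from 17.2 ± 2.72 CPM on P21 (n = 6) to 80.9 ± 38 CPM on P36 (n = 4), by 2.23 ± 0.32 (adjusted p = 4.92e-05). Sds, which degrades serine, rose by 2.16 ± 0.47 (adjusted p = 0.00226) and Ass1, of the urea cycle, by 1.14 ± 0.19 (adjusted p = 0.000149). Cyp4a10 fell from 2650 ± 696 to 506 ± 287 CPM, a log2 fold change of -2.39 ± 0.43 (adjusted p = 0.000245), and Derl3 fell with -3.73 ± 0.94 (adjusted p = 0.0088). Of 54 genes of amino acid breakdown 11 rose, 13 rose and 1 fell adjusted over the list alone (median 0.3, fry adjusted p = 0.0484, adjusted p = 0.374 with an estimated correlation). The urea cycle had 4 of 8 genes higher, 6 adjusted over the list alone (median 0.56, fry adjusted p = 0.00286, adjusted p = 0.169 with an estimated correlation). Of 14 gluconeogenesis genes 4 rose, 9 adjusted over the list alone (median 0.55, fry adjusted p = 0.00286, adjusted p = 0.169 with an estimated correlation), and without SG P36 library 1 a single one rose (median 0.45, fry adjusted p = 0.04). The count of called genes was 643 without SG P36 library 3. Whether the step differed between sham and SG mice was tested gene by gene only within the F test over the 3 diets, and no contrast of these diets alone was run, so the counts of 14 and 1237 are not shown to differ.

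**Figure D4:**
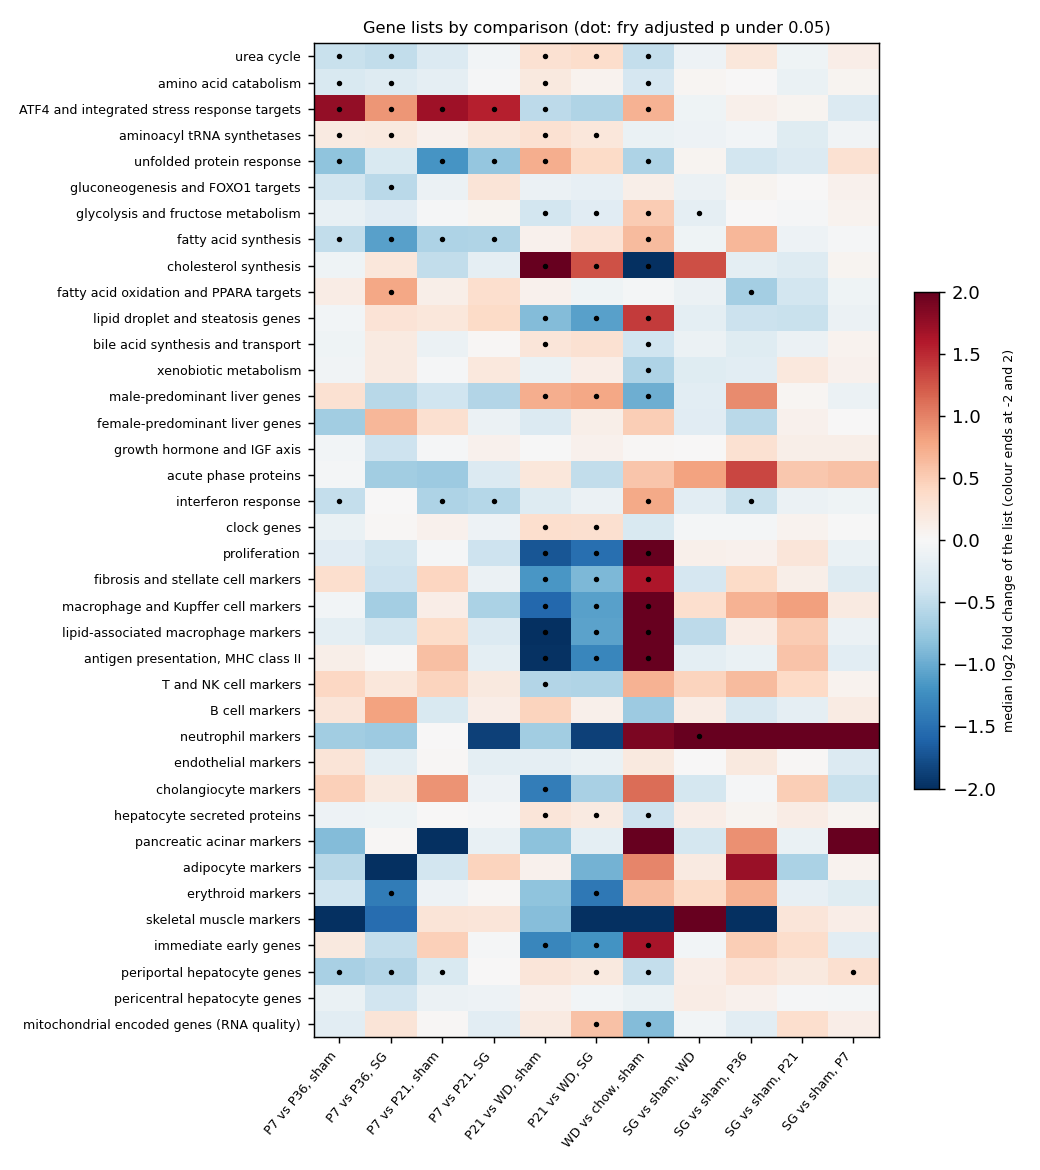
Heat map of the median log2 fold change of each gene list (rows) in 11 comparisons (columns), on a colour scale that ends at -2 and 2, with a dot where fry's test gave an adjusted p under 0.05. Cholesterol synthesis had medians of -2.45 for WD against chow and 3.13 for P21 against WD in sham mice, and ATF4 targets had a median of 1.75 for P7 against P36 in sham mice.

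The second question is what the operation did on each diet. On WD, SG livers held more transcripts of neutrophils and of the acute phase than sham livers, but chiefly in a pair of libraries. S100a8, a calcium-binding protein of neutrophils, stood at 115 ± 192 CPM after SG and 1.64 ± 1.83 CPM after sham surgery (n = 8 each), a log2 fold change of 6.16 ± 1 (adjusted p = 0.000119). Saa1, an acute phase protein, rose by 4.12 ± 1.15 (adjusted p = 0.0382) and Sqle by 4.13 ± 0.67 (adjusted p = 0.000119). Without SG WD libraries 5 and 7 these changes were 2.81 (adjusted p = 0.0896) for S100a8, 1.15 for Saa1 and 0.74 for Sqle, and limma-voom did not call Sqle (adjusted p = 0.306). Leaving out SG WD library 5 alone took Saa1 to an adjusted p of 0.188. Of 27 acute phase genes 0 were called without SG WD libraries 5 and 7 (median 0.29, fry adjusted p = 0.736).

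Lower after SG on WD, with or without those libraries, were Atp2b2, a calcium pump, at -2.2 ± 0.39 (adjusted p = 0.00053), Tkfc, an enzyme of fructose breakdown, and Dusp1, a phosphatase of MAP kinases. Tkfc fell from 698 ± 162 to 345 ± 109 CPM, a log2 fold change of -1.02 ± 0.18 (adjusted p = 0.000521), and Dusp1 from 46.9 ± 12.5 to 23.1 ± 5.15 CPM, with -1.02 ± 0.19 (adjusted p = 0.000916). Without SG WD libraries 5 and 7 the values were -1.89 (adjusted p = 0.0142) for Atp2b2, -0.91 (adjusted p = 0.0137) for Tkfc and -0.97 (adjusted p = 0.018) for Dusp1. Of 22 genes of glycolysis and fructose breakdown 5 fell, 6 fell and 1 rose adjusted over the list alone (median -0.18, fry adjusted p = 0.0135, adjusted p = 0.11 with an estimated correlation), and without those libraries 1 fell (median -0.2, fry adjusted p = 0.0309). All 10 neutrophil markers rose, 10 adjusted over the list alone (median 5.49, fry adjusted p = 0.0119, adjusted p = 0.11 with an estimated correlation), and none of them was called without SG WD libraries 5 and 7, though the list passed there too (9 markers tested, median 1.99, fry adjusted p = 0.0309). In all, 376 genes were called, 302 higher and 74 lower after SG, so that 80.3% were higher, and a fit of these groups alone called 2. The higher ones include 5 of 7 skeletal muscle markers, carried mainly by SG WD library 4. The count was 167 without SG WD library 5, 188 without library 7 and 66 without both, and limma-voom called 100, of which 49% were higher.

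On P36, SG livers had lower Dbp and Nr1d1, genes of the body clock, lower genes of fatty acid oxidation and higher Asns than sham livers. Dbp fell from 76.7 ± 10.5 CPM after sham surgery (n = 5) to 14.7 ± 6.42 CPM after SG (n = 4), a log2 fold change of -2.38 ± 0.38 (adjusted p = 0.000224), and Nr1d1 fell with -2 ± 0.26 (adjusted p = 9.65e-06). The highest SG library held 19.2 CPM of Nr1d1 and the lowest sham library 37.6 CPM. Bmal1, the clock activator that Nr1d1 represses, rose by 1.57 ± 0.39 (adjusted p = 0.0179, and 0.0785 without SG P36 library 4). The hour of day at which each liver was taken did not enter any fit. Its part in the clock genes, here and where P7 is compared with P36, was not tested. Asns rose from 1.57 ± 0.896 to 17.6 ± 9.64 CPM, by 3.5 ± 0.71 (adjusted p = 0.0033), and Scara5, a ferritin receptor, by 4.59 ± 1.03 (adjusted p = 0.00843). Fgf21 fell with -3.84 ± 0.97 (adjusted p = 0.0204), a call lost in 4 of the leave-one-out fits, at most 0.0859 without sham P36 library 2.

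Of 32 genes of fatty acid oxidation and PPARA targets 12 fell after SG on P36, 26 adjusted over the list alone (median -0.68, fry adjusted p = 0.0117, adjusted p = 0.259 with an estimated correlation). Bdh1, a dehydrogenase of ketone bodies, fell from 297 ± 68.7 to 153 ± 71.9 CPM, with -0.96 ± 0.21 (adjusted p = 0.00659), and Cyp4a10 fell with -2.09 ± 0.43 (adjusted p = 0.0033). Without SG P36 library 1 the list's adjusted p was 0.0544 and 6 of its genes fell. Of 30 interferon response genes 7 fell, 12 adjusted over the list alone (median -0.45, fry adjusted p = 0.0414, adjusted p = 0.288 with an estimated correlation), and that list had 0.0894 without the same library, with 3 lower. Isg15, an interferon-induced modifier, fell from 18.5 ± 8.29 to 6.49 ± 0.73 CPM, with -1.51 ± 0.29 (adjusted p = 0.00166). The metallothionein Mt2 (6.69 ± 1.47, adjusted p = 0.00704) and Hmox1, which breaks down haem (4.31 ± 0.64, adjusted p = 6.34e-05), rested on SG P36 library 1, with 0.99 and 0.89 without it. That library also had the highest mean of the erythroid markers in its group, 5.99 log2 CPM against 3.64 to 4.11 in the others. Its adipocyte markers had a mean of 4.24 log2 CPM, against -0.65 to 1.04, and the cause was not tested. In all, 357 genes were called, 196 higher and 161 lower, so that 54.9% were higher. A fit of these groups alone called 104, of which 66.3% were higher. The count was 169 without sham P36 library 2, 212 without sham P36 library 5, 175 and 172 without SG P36 libraries 3 and 4, and 561 without SG P36 library 2.

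On P21, single genes of several metabolic pathways were lower after SG. Pcx, pyruvate carboxylase, fell from 586 ± 74.8 CPM after sham surgery (n = 7) to 349 ± 35.7 CPM after SG (n = 6), a log2 fold change of -0.75 ± 0.16 (adjusted p = 0.00323). Its highest SG value of 396 CPM was under its lowest sham value of 483 CPM. Hadha, of mitochondrial fatty acid oxidation, fell with -0.73 ± 0.17 (adjusted p = 0.00617), and Srebf2, which drives cholesterol synthesis, with -0.73 ± 0.2 (adjusted p = 0.016). Csad, of taurine synthesis, fell from 321 ± 98.3 to 122 ± 74.7 CPM, with -1.39 ± 0.28 (adjusted p = 0.00272). Csf3r, a receptor of neutrophils, rose by 1.9 ± 0.46 (adjusted p = 0.00833), and Oas2, an antiviral enzyme, by 1.26 ± 0.31 (adjusted p = 0.00935). S100a8 (4.02 ± 1.05, adjusted p = 0.0135) and Orm2, an acute phase protein (3.02 ± 0.98, adjusted p = 0.0427), rested on SG P21 library 5, with 2.58 (adjusted p = 0.107) and 1.56 (adjusted p = 0.306) without it. Orm2 stood at 5.81 (adjusted p = 0.00308) without sham P21 libraries 1 and 2, which held more acute phase transcripts than the other 5 of their group (mean log2 CPM of the list 9.2 and 9.21, against 6.83 to 7.53).

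There were 1370 genes called on P21, 622 higher and 748 lower, so that 45.4% of calls were higher. A fit of these groups alone called 2354, and 868 were called without the filter on low counts. None of the 38 lists passed fry's test, the neutrophil markers included (9 of 10 higher, 10 adjusted over the list alone, median 3.82, fry adjusted p = 0.394, with 2 higher and a median of 2.45 without SG P21 library 5). In the authors' deposited table, 1244 genes passed on P21, 20.9% of them higher, and limma-voom without scaling of library sizes called 763, 178 higher and 585 lower.

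On P7 no gene was called between SG and sham livers by edgeR, with 681 at an unadjusted p under 0.05 and a lowest adjusted p of 0.25. DESeq2 called 7 genes and limma-voom 1. Asns stood at 50.6 ± 41.1 CPM after SG and 40.4 ± 16.4 CPM after sham surgery (n = 7 each), and Fgf21 at 41.5 ± 25.1 and 70.5 ± 70.2 CPM. The 14 periportal markers lay higher as a set after SG (median 0.32, fry adjusted p = 0.000587, adjusted p = 0.000315 with an estimated correlation; median 0.25 and fry adjusted p = 0.00326 without SG P7 library 7), with none called over all genes and 3 adjusted over the list alone. Hal had 261 ± 102 CPM after SG and 149 ± 51.1 CPM after sham surgery. In counts simulated at the sizes of these libraries, 82.1% of genes changed by 2-fold and 58.2% of those changed by 1.5-fold were recovered on P7. On P21 these were 83.6% and 52.2%. Apart from the planted changes, the simulation gave each gene a single mean and spread over all groups. The spread within SG P7, with library 7 apart, was thus not in it.

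**Figure D5:**
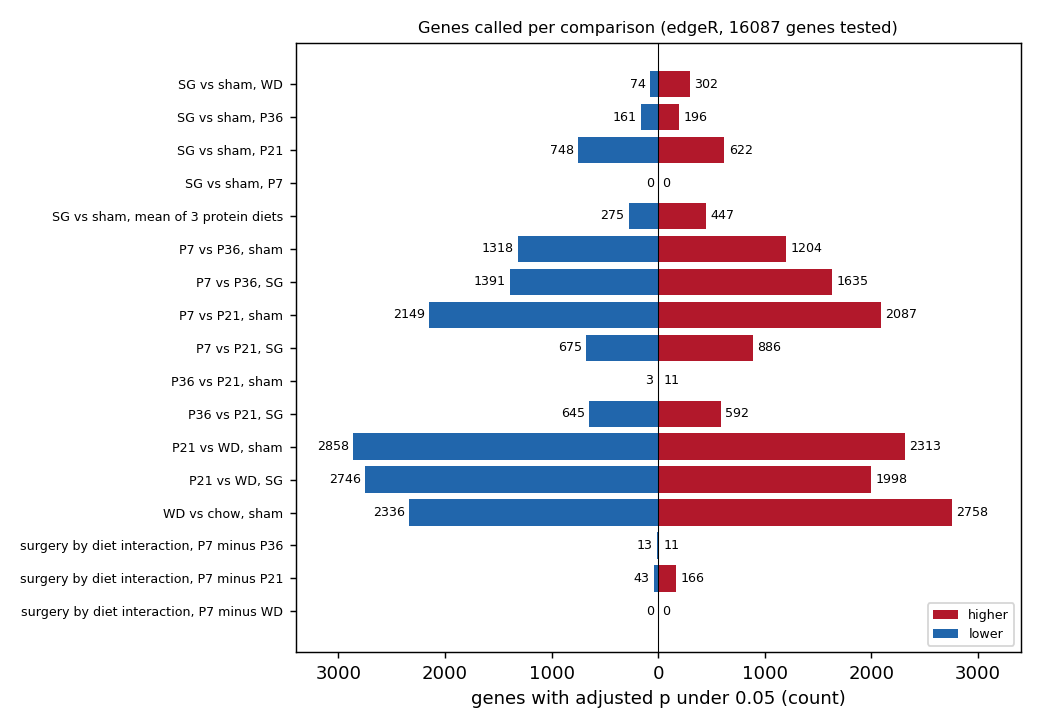
Number of genes called higher (bars to the right of 0) and lower (to the left) in each comparison by edgeR at an adjusted p under 0.05; the F test over 3 diets has no direction and is not drawn. The operation gave 376 calls on WD, 357 on P36, 1370 on P21 and 0 on P7, and P7 against P36 gave 2522 in sham and 3026 in SG mice.

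Averaged over the 3 protein diets, SG raised acute phase transcripts and lowered genes of fat burning. Orm2 rose by 3.19 ± 0.61 (adjusted p = 0.0017), Orm3 by 2.65 ± 0.41 (adjusted p = 0.000139) and Orm1 by 1.9 ± 0.33 (adjusted p = 0.000534), all members of the orosomucoid family of plasma proteins, whose sequences are alike enough to share reads. Of 27 acute phase genes 13 rose, 23 rose and 1 fell adjusted over the list alone (median 0.77, fry adjusted p = 0.0116, adjusted p = 0.223 with an estimated correlation), with 7 rising without SG P21 library 5 and 21 without sham P21 libraries 1 and 2. All 10 neutrophil markers rose too, 10 adjusted over the list alone, though the list did not pass (median 2.92, fry adjusted p = 0.0689; 7 higher and a median of 2.25 without SG P36 library 1), with S100a9 at 3.09 ± 0.6 (adjusted p = 0.00171). Of 32 genes of fatty acid oxidation and PPARA targets 17 fell, 24 adjusted over the list alone (median -0.39, fry adjusted p = 0.00385, adjusted p = 0.167 with an estimated correlation), among them Acadm, which oxidizes medium-chain fatty acids, with -0.48 ± 0.1 (adjusted p = 0.00345). Of 14 periportal markers 4 rose, 6 adjusted over the list alone (median 0.25, fry adjusted p = 0.000375, adjusted p = 0.0654 with an estimated correlation). Csad fell with -1.19 ± 0.17 (adjusted p = 6.33e-05) and Isg15 with -0.82 ± 0.14 (adjusted p = 0.000455). In all, 722 genes were called, 447 higher and 275 lower, and 428 without SG P36 library 1. limma-voom called 395, of which 51.4% were higher against 61.9% here.

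The effects of surgery on different diets correlated weakly across genes. Between WD and P36 r was 0.25 and rho 0.18, between WD and P21 0.38 and 0.31, between P36 and P21 0.28 and 0.26, between WD and P7 0.38 and 0.22, between P36 and P7 0.22 and 0.09, and between P21 and P7 0.22 and -0.01. Of the genes called on WD and on P21, 63 were higher in both, against 11.7 by chance, and 0 lower in both, against 3.44 by chance. On P36 and P21, 17 were higher in both, against 7.58 by chance, and 13 lower, against 7.49 by chance.

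A test of whether the surgery effect differed among the 3 protein diets called 209 genes. Nr1d1 (F test, adjusted p = 0.00625) had a log2 fold change of SG against sham of -2 on P36, -0.49 on P21 and -0.16 on P7, and Dbp (adjusted p = 0.0163) had -2.38, -0.05 and -0.24. Flt1, a receptor of vascular growth factor (adjusted p = 0.006), had 0.81, -0.1 and -0.36. Furin, a protease that matures secreted proteins (adjusted p = 0.0163), had -0.05, -0.8 and 0.24. Between P7 and P21 the effect differed in 209 genes, 166 with the higher value on P7. Between P7 and P36 it differed in 24, 11 with the higher value on P7, but in 3 by a fit of these groups alone, where chance could not be excluded. The splits of the libraries could not exclude chance for the other differences between diets either, as they tested for no surgery effect on any diet. Between P7 and WD it differed in 0 genes by edgeR, with 794 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom. The counts also moved with the method, from 59 without the filter on low counts to 495 by DESeq2 over 3 diets, from 3 in the fit of the compared groups to 89 by DESeq2 for P7 against P36, and from 91 without the filter to 482 by DESeq2 for P7 against P21. They hung on single libraries too, from 32 without SG P21 library 4 to 512 without sham P7 library 7 over 3 diets, from 6 without sham P36 library 5 to 115 without SG P36 library 2 for P7 against P36, and from 39 without SG P7 library 7 to 731 without sham P7 library 2 for P7 against P21.

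The authors' deposited table holds log2 fold changes and adjusted p-values of SG against sham on the 3 protein diets for 15523 genes. Its log2 fold changes correlated across genes with those computed here at r = 0.91 on P21, 0.93 on P36 and 0.88 on P7, and with those of limma-voom without scaling of library sizes at r = 1, rounded to 2 decimals, on each of the 3 diets. Genes are not independent replicates. The authors' deposited table called 1244 genes on P21, 250 on P36 and 1 on P7, and 975, 229 and 0 of them were called here in the same direction. In the authors' deposited table Asns on P36 had a log2 fold change of 3.57 (adjusted p = 0.0267), and Fgf21 had -3.8 (adjusted p = 0.433). The gene past the threshold on P7 in the authors' deposited table was Krt23, a keratin, with -1.89 (adjusted p = 0.00691), named after its values were seen.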

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

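Most tests of explanations below were chosen after the results were seen. Chosen before were the position of SG WD libraries 5 and 7 between WD and P21, and the splits of the libraries, except those of SG against sham on P36.

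SG P7 library 7 lay apart from the other 6 libraries of its group in 4 of the genes checked, with log2 CPM of -0.37 for Fgf21, 0.14 for Gdf15, 9.29 for Igf1 and 0.25 for Igfbp1. Its depth of 23.59 M counts was inside the 23.01 to 33.36 M of the other 6, which argues against low depth. On the axis from sham P21 (0) to sham P7 (1) it stood at 0.19, against 0.75 to 1.07 in the other 6, so a wrong diet label may account for it. On the axis from sham P21 (0) to sham chow (1) it stood at 0.84, against 0.20 to 0.45 in the other 6, 0.93 to 1.06 in sham chow and 0.95 in the SG chow library, so a chow-fed animal is another candidate explanation. Both stay open as hypotheses, and a biological cause in this mouse was not tested.

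SG WD libraries 5 and 7 held 14.03 and 13.51 log2 CPM of Saa1, against 7.71 to 9.77 in the other 6 of their group, and high cholesterol genes beside it. A lower-fat diet under the WD label is argued against, since their positions on the axis from sham WD (0) to sham P21 (1) were 0.11 and 0.16, both inside the -0.21 to 0.26 of the other 6 and far from the 0.94 to 1.14 of sham P21. Blood left in the liver is argued against by the erythroid markers, whose higher mean was 4.89 log2 CPM, inside the 4.07 to 5.49 of the other 6. An illness or infection of these mice stays open and could not be tested with these files, so the values 0.11, 0.16 and 4.89 only narrow what may have happened.

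No gene was called by edgeR between SG and sham on P7, with 681 at an unadjusted p under 0.05, 7 by DESeq2 and 1 by limma-voom. Leaving out SG P7 library 7 still gave 0, which argues against its spread as the whole cause. An effect as on P21 hidden by the spread is argued against, because the 1370 genes called on P21 had a median log2 fold change on P7 of -0.02 when signed as on P21, under the 0.13 on P36 and the 0.11 on WD, with their own median on P21 at 0.60. These genes thus showed little of that size on any other diet. The 376 genes called on WD kept their sign on P7 in 77.9%, with a median of 0.28 against their own 1.73, so some effect of surgery on P7 stays open. A smaller effect of surgery on P7 than on P21 is a hypothesis that would be in line with the 39 genes called by the interaction test without library 7, fewer than the 209 with it. The genes were chosen on P21, where chance enlarges the effect, so part of the gap to 0.60 may come from that choice.

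Of 270 checks of single libraries, 17 gave a library far from the rest of its group, while chance alone flags about 5% of the 270, not far below this number. In sham WD these were Fgf21 in library 1 (6.19 log2 CPM) and Cpt1a in library 2 (8.36). Sham chow library 1 stood apart in Pck1 (10.53), Cyp8b1 (9.43) and Cyp2b9 (4.46). Sham P21 library 3 had Sqle at 6.01 log2 CPM. In sham P36, library 6 had Igf1 at 9.36 and library 2 Fasn at 8.16. Saa1 was at 4.8 log2 CPM in SG P36 library 2 and at 9.87 in SG P7 library 6. SG P21 library 4 had 6.99 M counts and 17066 genes detected.

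The effect of surgery differed between diets by a test of the difference itself in 209 genes over P36, P21 and P7, in 24 between P7 and P36 and in 209 between P7 and P21. For P7 and P36 chance could not be excluded, since a fit of these groups alone gave 3 genes and 8 of 100 splits of the libraries gave as many, with 231 at most. For the other interactions the splits cannot exclude chance either. They swapped labels of surgery within each diet and so tested for no surgery effect on any diet, not for an equal one. As log2 ratios of fold changes, P7 over P36, the values were 2.14 for Dbp, 2.02 for Raet1d, 1.84 for Nr1d1, 1.81 for Rcan2, 1.54 for Crat and 1.40 for Serinc2. On the other side stood Hmox1 with -4.26, Akr1b8 with -2.04, Btg3 with -2.03, Slc1a4 with -2.01, Srrm4 with -1.92 and Akap12 with -1.81. Without SG P36 library 1, Hmox1 was at -0.84, Akr1b8 at -0.67, Btg3 at -1.23 and Akap12 at -1.16. For P7 over P21 they were 1.52 for Tnfrsf14, 1.45 for Cmip, 1.31 for Car5a, 1.30 for Fbxo21, 1.28 for Arfgap3 and 1.24 for Sec14l4. Cib3 had -3.33, Osmr -1.32, Zfp708 -1.24, Igfbp7 -1.19, Ifi203 -1.08 and Lipt2 -1.08, and Cib3 was at -2.24 without SG P21 library 3. Apart from Nr1d1, Igfbp7 and Ifi203, each of these calls was lost without at least 1 library, with the highest adjusted p without SG P36 library 1 or 4, SG P21 library 3 or SG P7 library 7.

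The single SG chow library, which entered no comparison, held 4.45 log2 CPM of Asns against a mean of 1.70 (SD 0.57, n = 4) in sham chow, 9.68 of Igf1 against 9.46 (SD 0.06) and 8.97 of Saa1 against 3.53 (SD 0.07).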

How the results depend on the processing

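The fits without scaling and without libraries that lay apart were chosen after the data were seen. Of 1501 values of single genes, RLE scaling kept direction and side of the threshold in 1493, DESeq2 in 1477 and limma-voom in 1281, with 220 calls lost in limma-voom. Of the fits that left out 1 library, only those with the lowest and the highest log2 fold change were counted here. They kept direction and side in 1296 and 1325 of the values, which include genes that were not called. Calls could also be lost in other such fits. For SG against sham on WD, Saa1 lost its call in 9 of 16 and S100a8 in 0. Of 646 list results 551 kept theirs under camera with an estimated correlation, 95 being lost, and 507 with a preset one, 135 being gained. The correlation of 0.58 between the diet effects in sham and SG mice was 0.72 over the genes called in either. RLE scaling moved no share of higher calls by over 10 percentage points. No paired analysis was possible because the numbers of the libraries only name animals within a group, and no animal is in more than 1 group.

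For SG against sham, limma-voom called 100 genes on WD, 1 on P7 and 395 over the 3 diets, and DESeq2 7 on P7. A fit of the compared groups alone called 2 on WD, 104 on P36 and 2354 on P21. Without the filter 868 were called on P21, and limma-voom without scaling called 763 on P21 and 1 on P7. Without SG WD libraries 5 and 7 there were 66 calls on WD and 1 for the interaction of P7 and WD. Between diets, no filter gave 1021 for P7 against P21 in SG mice. For P36 against P21 in sham mice limma-voom called 4, DESeq2 36, the fit of the compared groups 62 and the fit without sham P21 libraries 1 and 2 called 3. For the interaction over 3 diets these were 112 by limma-voom, 495 by DESeq2, 365 for the compared groups and 137 without those libraries, with 59 when unfiltered. For P7 against P36 they were 13 unfiltered, 10 by limma-voom, 89 by DESeq2 and 3 for the compared groups, and for P7 against P21 91 unfiltered, 482 by DESeq2 and 118 without sham P21 libraries 1 and 2. For P7 against WD DESeq2 called 4. The cause was not tested. The share of higher calls was 49% by limma-voom and 50% in the compared groups alone on WD, against 80.3%, and 66.3% in the compared groups alone on P36, against 54.9%.

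Leaving out each library in turn, SG against sham gave 167 to 522 genes on WD, 169 to 561 on P36, 966 to 1438 on P21, 0 to 1 on P7 and 428 to 1015 over 3 diets. P7 against P36 gave 2052 to 2677 in sham and 2071 to 3483 in SG mice, P7 against P21 3562 to 4568 and 944 to 1637, and P36 against P21 4 to 24 and 643 to 1378. P21 against WD gave 4415 to 5967 and 3628 to 4893, and WD against chow 3927 to 5794. The interactions gave 32 to 512 over 3 diets, 6 to 115 for P7 against P36, 39 to 731 for P7 against P21 and 0 to 4 for P7 against WD. The ends were set by SG WD library 5 and sham WD library 4 on WD, sham P36 library 2 and SG P36 library 2 on P36, sham P7 library 7 on P7, and SG P36 libraries 1 and 2 over 3 diets. The cause was not tested.

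Directions turned in a few genes among the fits that left out 1 library, given here as lowest to highest log2 fold change. In P7 against P36 after SG, Mt2 ran from -7.00 to 1.29, Plin1 from -5.26 to 0.45, Adipoq from -5.10 to 0.05, Trarg1 from -2.35 to 0.45, Slc4a1 from -3.03 to 0.25, Fosl1 from -3.85 to 0.19 and Ier3 from -1.75 to 0.49. In P36 against P21 after SG, Mt2 ran from -1.69 to 8.46, Fabp4 from -0.13 to 2.40, Ier3 from -0.24 to 2.00 and Fosl1 from -0.11 to 4.02. The end on the other side of 0 came without SG P36 library 1 in each of these. Cyp2b10 in P7 against P21 after SG ran from -0.19, without SG P7 library 7, to 4.30. In P21 against WD after SG, Slc5a1 ran from -3.09 to 0.50 and Epcam from -2.23 to 0.50, the higher end without SG WD library 1, and Slc5a1 was at 0.44 by DESeq2. The cause was not tested. Depth limits mainly SG P21 library 4, with 6.99 M counts.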

Other observations

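Values of gene groups that the report does not describe are given first. Of the tests of this part, the splits of the libraries of SG against sham on P36 and the fits without sham P21 libraries 1 and 2 were chosen after the result was seen.

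Markers of skeletal muscle, macrophages and cholangiocytes and the immediate early genes come first, and where the muscle transcripts came from was not tested. Of 7 skeletal muscle markers 5 rose after SG on WD, 6 adjusted over the list alone (median 4.27, fry adjusted p = 0.79). Ckm, the creatine kinase of muscle, had a log2 fold change of 4.72 ± 1.17 (adjusted p = 0.0146), with 2.40 log2 CPM in SG WD library 4, -0.13 in library 1 and -3.67 in each of the other 6. Acta1, muscle actin, had 3.47 log2 CPM in library 4 and -3.67 to -2.05 in the other 7. Macrophage markers followed the diet, with 18 of 22 higher in sham mice on WD than on chow, 20 adjusted over the list alone (median 2.4, fry adjusted p = 7.36e-06, adjusted p = 0.143 with an estimated correlation). Itgax, an integrin of such cells, rose by 4.18 ± 0.53. Of 16 immediate early genes 11 fell from WD to P21 in sham mice, 13 adjusted over the list alone (median -1.31, fry adjusted p = 1.53e-05, adjusted p = 0.149 with an estimated correlation). Egr2 had a log2 fold change of -2.96 ± 0.5 and Jun one of -1.61 ± 0.31. Of 12 cholangiocyte markers 8 fell there, 10 adjusted over the list alone (median -1.39, fry adjusted p = 0.00833, adjusted p = 0.455 with an estimated correlation), among them Spp1, osteopontin, with -2.4 ± 0.4.

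Of 31 genes of xenobiotic metabolism 12 fell and 1 rose on WD against chow in sham mice, 12 and 1 adjusted over the list alone (median -0.62, fry adjusted p = 0.0231, adjusted p = 0.541 with an estimated correlation). Cyp2b10, a drug-metabolizing enzyme, had a log2 fold change of -4.32 ± 0.91 and Ces2a, a carboxylesterase, one of -1.92 ± 0.31. Interferon response genes rose on WD in the same comparison, 17 of 30 with 3 lower, 18 and 3 adjusted over the list alone (median 0.75, fry adjusted p = 5.86e-05, adjusted p = 0.218 with an estimated correlation). Oas1a rose by 2.56 ± 0.25.

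Lepr, the leptin receptor, rose from 1.98 ± 0.427 CPM on P36 (n = 5) to 21.8 ± 15.4 CPM on P7 (n = 7) in sham mice, a log2 fold change of 3.46 ± 0.48 (adjusted p = 6.14e-07). Igfbp1, which binds growth factors, rose by 3.29 ± 0.78 (adjusted p = 0.00215), and Igf1 fell with -0.75 ± 0.16 (adjusted p = 0.000485).

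Sham WD library 3 stood at 0.70 on the axis from sham WD (0) to sham P21 (1), against -0.34 to 0.23 in the other 7 of its group. Sham P21 libraries 1 and 2 held 11.4 and 11.92 log2 CPM of Saa2, against 3.06 to 5.74 in the other 5 of their group, 6.63 and 6.12 of Mt1, against 0.07 to 1.51, and 6.75 and 5.92 of Derl3, against 3.52 to 4.63. Without them the log2 fold change of Saa1 went from 1.68 (adjusted p = 0.23) to -2.92 (adjusted p = 0.0569) for P21 against WD in sham mice. For SG against sham on P21 it went from 1.02 (adjusted p = 0.622) to 5.61 (adjusted p = 0.0111). With them kept and SG P21 library 5 left out, Saa1 for SG against sham on P21 was at -1.72, so its direction hung on the libraries kept.

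To ask whether chance could give as many calls, the libraries of each comparison were split in other ways into groups of the same sizes. In a fit of the compared groups alone, 100 splits were drawn, the real one counted. Where more than 2 groups were compared, labels of surgery were swapped within each diet. Chance was taken as excluded where under 5% of the splits gave as many. Mice were moved singly, so shared cages, which are not known, were not allowed for. By this rule chance is excluded for SG on P21 (2354 genes, 1 split as large, 14 at most in others) and over 3 diets (1048, 1 split, 220). On P36 the real groups gave 104 and 2 of the 100 splits gave as many, a share under which chance would be excluded, but the other of these gave 182, more than the real groups. On WD the real groups gave 2 genes and 4 splits gave as many, a share under which chance would be excluded, but another split gave 1203, which points to a structure of the samples. On P7 the real groups gave 0 by edgeR in this fit, with 1 at most in others. Each of the 100 splits reaches a count of 0 by construction, so the splits say nothing there about chance.

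For P7 against P36 the real split gave 2281 genes in sham and 2173 in SG mice, with 291 and 1321 at most in others, and for P7 against P21 4120 and 2090, with 162 and 2. P36 against P21 gave 62 and 998, with 36 and 113 at most in others. P21 against WD gave 4610 and 3208, with 1204 and 2434, and WD against chow 4666, with 447. By the same rule chance is excluded in each of these, as only 1 of the 100 splits, the real one, was as large. The 62 genes for P36 against P21 in sham mice belong to this fit, and the fit of all groups called 14. For the interactions over 3 diets (365, 57 at most in others) and for P7 against P21 (172, 12), only the real split was as large. These splits swapped sham and SG labels within each diet, so they set the counts against no effect of surgery on any diet. They do not set them against an equal effect on each diet, and so cannot exclude chance for a difference between diets. For P7 against P36 the interaction gave 3 genes and 8 splits gave as many, with 231 in another, so chance could not be excluded, and the split with 231 points to a structure of the samples that was not tested. For P7 against WD it gave 0, with 6 at most in others, and the splits say nothing there either.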
